A study of Mus musculus with 18 samples.

How the data were processed

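CTCF chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in mouse embryonic stem cells of 3 genotypes: wild type (WT), a line without Tet1, Tet2 and Tet3 (TKO), and a line without those genes and without Dnmt1, Dnmt3a and Dnmt3b (SKO). The labels give 3 ChIP and 3 input samples per genotype, 18 samples in 6 groups, and do not say whether the replicates came from separate cultures. Per the labels' protocols, the cells were grown on irradiated mouse embryonic fibroblasts, so the lysates may hold some feeder chromatin, and the libraries were selected on a gel for fragment size and amplified by PCR. Molecular identifiers are not mentioned. Peaks were called on pooled replicates, so the counting intervals given here cover counting error only.

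The 3 files used hold peak lists, 1 per genotype, and per the labels each was called by the authors on the 3 replicates pooled, ChIP against input. The submitters' processing notes name FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0, deepTools 3.5.0 and the mm10 build; the commands and read filters are not given in the sources used here. In each deposited list a peak carries its fold enrichment, the ratio of ChIP pileup to local background at the summit as the authors' peak caller gave it. Each deposited peak also carries a −log10 p and a −log10 q, and the lowest −log10 q was 1.30 in the WT and TKO lists and 1.31 in the SKO list, at a q of 0.05. These values are the authors' own and were used to describe, rank or filter peaks within a list. The fold, and the pileup and background solved from fold and −log10 p, were also compared between lists. Those comparisons concern depth, enrichment and the H19 region. Because replicates were pooled before peak calling, no spread between replicates could be computed and no p-value between genotypes is reported.

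Rows with the same interval and different summits were joined into 1 region with its strongest summit, which gave 71075 WT regions from 73125 summit rows, 62238 TKO regions from 64121 rows and 59372 SKO regions from 61027 rows. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. A peak of the first-named genotype with no such partner is called lost and a peak of the other genotype with none is called gained, words that describe membership of the lists. Peaks of all 3 lists were merged into regions for the classes. The same counts of unmatched peaks came from bedtools 2.31.1. Shares carry 95% Wilson intervals, and shares per chromosome exact binomial intervals.

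Loss was compared among peaks of like strength. Each list was divided into 10 bins of equal size by −log10 q, and 10000 random sets with the same number of peaks per bin gave the range and the percentile of an observed count, with ties split evenly. Such a percentile describes these lists and is not a p-value. The depth behind each list was read from the values: fold and −log10 p together return a whole-number ChIP pileup (relative error under 1e-04) for 99.5% of WT rows, 99.6% of TKO rows and 99.7% of SKO rows, and the lowest background returned is the genome-wide one. It was 1.76 in WT, 1.82 in TKO and 1.37 in SKO, in fragments over a position. Read totals per sample were not used here.

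Genes came from the RefSeq table of GRCm38.p6, the assembly behind mm10, with 49943 genes of which 21887 are protein-coding. It gives a gene's start and end without strand or exons, so "gene end" below means either boundary; promoters, exons and introns, as planned, could not be told from it. As a check of the coordinates, 8.54% of WT summits lay within 1 kb of a protein-coding gene end, against 5.63% after moving the same summits by 20 kb. A peak is named by the protein-coding gene that holds its summit (the shortest where several do) or else by the nearest boundary within 100 kb. Gene lists took peaks whose summit lay in a gene or within 10 kb of it. The 13 lists were pluripotency genes, imprinted genes, clustered protocadherins, Hox genes, germline genes, genes of the 2-cell-like state, NuRD subunits, chromosome architecture factors, DNA methylation enzymes and readers, the X inactivation centre, feeder fibroblast markers, early lineage genes, and silencers of endogenous retroviruses. Every symbol was matched, some through synonyms, except 1 of the X inactivation centre.

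The genes and peaks named were chosen by a rule. For each comparison it takes the 6 lost and 6 gained peaks of highest fold in their own list on the autosomes and X, the 4 genes with most lost and the 4 with most gained peaks, and up to 4 genes per list with most changes. It always takes the genes of the 6 deleted enzymes, H19 and Ctcf. Some items that the rule takes are not reported here. Further regions are marked where they appear as chosen after their values were seen.

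The gene lists, this rule and the alternatives were fixed before the data were examined. In naming peaks, the nearest gene boundary replaced the planned nearest transcript start, because the gene table has no strand. Gene ends likewise replaced the planned promoters. The alternatives were a reciprocal overlap of 50%, summits within 100 bp, a −log10 q of at least 5, a fold of at least 5, the 30000 strongest peaks of each list, a −log10 q of at least 10 in the queried list alone, peaks scaled to the lowest background, and chromosomes 1 to 19. Shortening the lists to the length of the shortest was added after seeing the data. Comparisons that need the genome sequence (CTCF motifs with a CpG, CpG density and repeats) were planned and are not analysed here. The methods were tested on simulated data: the pileup was recovered for 100.0% of 4967 simulated peaks, a set of 200 WT regions with doubled loss stood at percentile 100.0, and 4.80% of 1000 unrelated features of the WT regions fell outside the central 95%. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.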

Results

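CTCF binds DNA through its zinc fingers and, with cohesin, anchors chromatin loops. CpG methylation inside its motif is known to hinder binding at some sites. The TET enzymes oxidise methylated cytosine and the DNMT enzymes methylate it, so the TKO line lacks the former and the SKO line lacks both. The lists therefore allow 3 comparisons: which CTCF peaks are missing or extra without the TET enzymes, which are missing or extra when the methyltransferases are gone as well, and what separates the knockouts from each other. Each list pools 3 ChIP replicates, so a peak has no replicate values, and the intervals given with shares cover counting error only. Each genotype is also a separate line, so effects of the missing enzymes cannot be told from other differences between the lines.

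The WT list was the longest. It held 71075 regions covering 26.6 Mb, against 62238 regions and 23.3 Mb in TKO and 59372 regions and 22.8 Mb in SKO. Median fold enrichment, the authors' value in each list, was 10.0 in WT (quartiles 6.17 and 15.4), 9.84 in TKO (6.34 and 14.5) and 10.5 in SKO (6.61 and 15.8). The genome-wide background of the TKO list was 1.04 times that of WT, and that of the SKO list was 0.779 times that of WT.

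Merging the lists gave 78072 regions, of which 51763 (66.3%) held a peak in all 3 genotypes. Regions with a WT peak alone numbered 9934 (12.7%), those with WT and TKO peaks 5603, those with WT and SKO peaks 3524, those with a TKO peak alone 3359 and those with an SKO peak alone 2610. TKO and SKO shared 1279 regions (1.64%) without a WT peak.

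**Figure D1:**
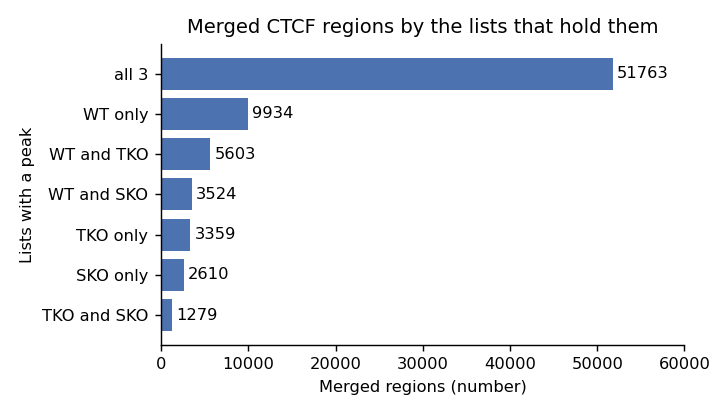
Number of merged CTCF regions (horizontal axis) by the lists with a peak there (vertical axis). Regions in all 3 lists number 51763, and regions in the WT list alone, 9934, are the next class.

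The genes of the deleted enzymes differed in their numbers of CTCF peaks, which count peaks in each list whether or not they overlap. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907206 to 20959888), had 6 peaks in the gene or within 10 kb in each list, and all 6 WT peaks were shared. Tet1 (chromosome 10, 62804570 to 62887469) had 9 peaks in WT, 8 in TKO and 6 in SKO. Tet2 (chromosome 3, 133463677 to 133545136) had 5, 4 and 2, and Tet3 (chromosome 6, 83362373 to 83457208) had 2, 2 and 1. The de novo methyltransferase gene Dnmt3a (chromosome 12, 3801559 to 3914443) had 7, 5 and 6 peaks, and its paralogue Dnmt3b (chromosome 2, 153649411 to 153687730) had 4, 5 and 2. Ctcf itself (chromosome 8, 105636474 to 105682922) had 4 peaks in WT and 2 in each knockout. The WT peaks missing there from both knockouts were weak, at −log10 q 2.59 and 2.73. They lie in the weakest WT decile, where 70.4% of peaks were missing from TKO and 76.9% from SKO. A CTCF peak near a gene says nothing about whether the gene was deleted unless it lies in the deleted part, which the labels do not give, so these peak numbers do not check the genotypes.

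The first comparison asked what changed without the TET enzymes. Of the WT peaks, 13492 (19%, 95% interval 18.7% to 19.3%) had no TKO peak over them, and 4663 TKO peaks (7.49%, 7.29% to 7.70%) had no WT peak. The WT peak of highest fold missing from TKO lay on chromosome 17 (80860541 to 80860947, fold 19), 83.9 kb from Tmem178. The next with a gene to name lay upstream of H19, an imprinted non-coding RNA, on chromosome 7 (142581631 to 142582184, fold 17.6), with Mrpl23 the nearest protein-coding gene at 41.1 kb. The others lay inside Cd163, the haemoglobin scavenger receptor of macrophages (chromosome 6, 124317370 to 124317711, fold 17.5), 41.5 kb from Atp6v1c1, a subunit of the vacuolar proton pump (chromosome 15, 38620223 to 38620522, fold 17.4), inside Fign, a microtubule-severing protein (chromosome 2, 64013111 to 64013456, fold 16.7), and on chromosome 12 (110154630 to 110154983, fold 18.9) with no protein-coding gene within 100 kb. The SKO list held 4 of these 6 peaks and lacked those near Tmem178 and H19.

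The strong TKO peaks absent from WT included a peak inside the solute carrier gene Slc10a7 (chromosome 8, 78701908 to 78702192, fold 12.3) and a peak inside Kynu, an enzyme of tryptophan breakdown (chromosome 2, 43636512 to 43636802, fold 11.7). Others lay near the kinase gene Pak6 (9.27 kb away, fold 11.2), the xylosyltransferase gene Xxylt1 (1.41 kb, fold 11.1) and the kainate receptor gene Grik2 (73.9 kb, fold 11.1). The peaks by Slc10a7, Kynu and Grik2 also had an SKO peak.

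Counted by gene, the 4 with most losses were long. Nav2, a cytoskeletal regulator of neurite growth that is 651 kb long, lost 12 of 36 WT peaks. The acid-sensing channel gene Asic2 (1088 kb) lost 11 of 36, the synaptic scaffold gene Magi2 (1485 kb) lost 10 of 19, and Rere, a nuclear receptor coregulator (340 kb), lost 10 of 24. Gains per gene reached 4, among others at Sfi1 (a centrosomal protein, 9 TKO peaks), Oxr1 (an oxidation resistance protein, 10) and Cfap77 (a ciliary protein, 11).

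The loss was concentrated in weak peaks. In the weakest decile of the WT list 70.4% of peaks (69.3% to 71.5%) were missing from TKO, in the middle of the list, at the fifth decile, 6.95% (6.38% to 7.56%), and in the strongest decile 0 of 7107, which allows up to 0.0540%. Among the 35537 WT peaks above the median −log10 q, 127 (0.357%, 0.30% to 0.425%) were missing. Lost WT peaks had a median fold of 5.08 and shared WT peaks one of 11.9.

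Gene ends lost fewer peaks than their strength would give and gained more. Of lost WT peaks 7.37% (6.94% to 7.82%) lay within 1 kb of a protein-coding gene end, against 11% of shared WT peaks of the same strength (10.1% to 11.8% in the central 95% of sets). Of gained TKO peaks 13.2% (12.3% to 14.2%) lay there, against 9.35% of shared TKO peaks of the same strength (8.34% to 10.4%). These differences kept their direction with a window of 2.5 kb, with all gene biotypes and with a −log10 q of at least 5.

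With genes and 10 kb either side, none of the 13 gene lists lost WT peaks in TKO outside the central 95% of random sets of the same strength. On the low side, 3 lists did so under an alternative: methylation enzymes and readers with 50 kb either side (17 of 155 peaks, 28.1 in matched sets, percentile 0.0900), germline genes with gene bodies alone (percentile 0.695) and feeder fibroblast markers at a −log10 q of at least 5 (percentile 0.885). The imprinted list came nearest on the high side, with 26 of 140 peaks lost where matched sets lost 21.2 on average (percentile 92.8, and 98.6 with summits within 100 bp). Its members with most changes were Zfp64 (5 of 16 peaks lost), Trappc9 (3 of 10), Gnas, which encodes a G protein subunit (2 of 6), and Airn, the non-coding RNA that silences Igf2r (1 of 4, with 1 gained). Among NuRD subunit genes 17 of 90 peaks were lost (19 on average in matched sets), led by Gatad2b with 4 of 13, Zmynd8 and Chd5 with 2 each, and Rbbp7 with 1. Chromosome architecture genes lost 16 of 85 peaks (18.9), with 3 at the cohesin loader gene Nipbl, 3 at the cohesin subunit gene Stag1, 2 weak ones at Ctcf and both WT peaks of Stag2. Pluripotency genes lost 18 of 92 (17.6), of which the orphan receptor gene Esrrb had 3, and the growth factor gene Gdf3 and the nuclear receptor gene Nr5a2 2 each.

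In the remaining lists the losses in TKO were 19 of 103 peaks for germline genes (24.7 on average in matched sets), with 3 each at Tex14, Brdt and Tex11; 7 of 85 for clustered protocadherins (8.36); 5 of 34 for Hox genes (5.62); and 13 of 81 for early lineage genes (13.8), with 2 each at Pou3f1, Dnmt3a and Lamb1. Silencers of endogenous retroviruses lost 13 of 77 (15.2), with 2 each at Kdm1a, Morc2a, Sumo2 and Pphln1. The methylation enzyme and reader genes lost 9 of 58 (11), the X inactivation centre 5 of 23 (7.50), with 3 at the overlapping Xist and Tsix, and genes of the 2-cell-like state 2 of 18 (2.29). Feeder fibroblast markers lost 6 of 58 (10.0), including 2 at the fibronectin gene Fn1 and 1 at the collagen gene Col5a1. Gains in TKO fell outside the central 95% for 1 list, the imprinted genes, with 2 of 116 TKO peaks where matched sets gained 6.29 (percentile 1.71). The imprinted value lay inside for gene bodies alone (percentile 11.1), with 50 kb either side (4.48) and with summits within 100 bp (26.3), while germline genes lay below with gene bodies alone (0.825) and with 50 kb either side (0.835).

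**Figure D2:**
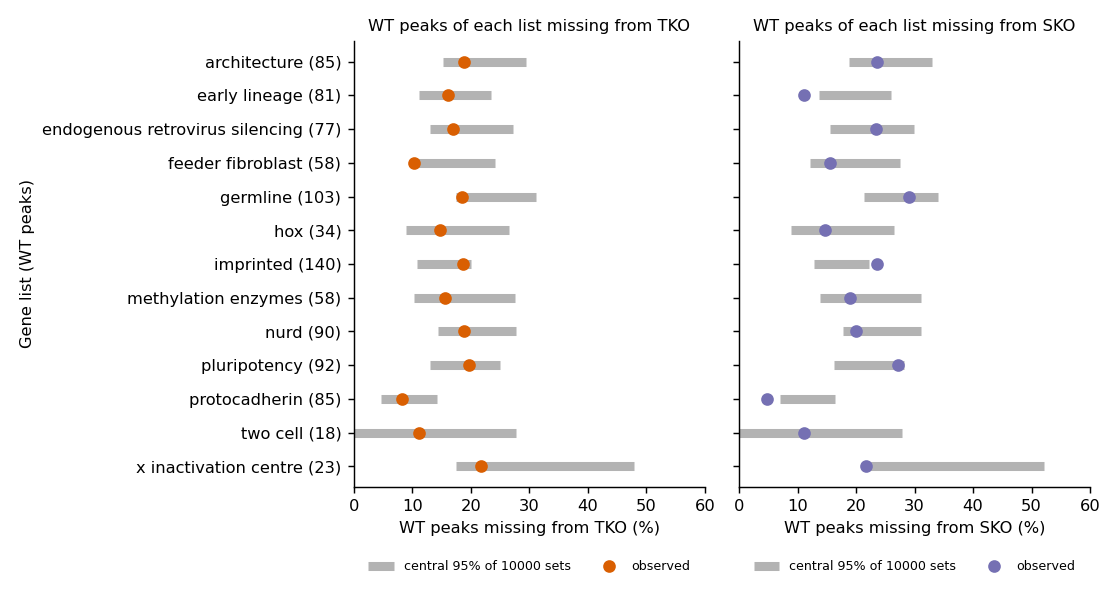
Share of WT peaks missing from TKO (left) and SKO (right) for each gene list, in percent, with the number of WT peaks in brackets. Points are observed shares and grey bars the central 95% of 10000 random sets of WT peaks of the same strength; imprinted genes (33 of 140 peaks) lie above the bar in SKO, and clustered protocadherins (4 of 85) and early lineage genes (9 of 81) below it.

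The second comparison asked what changed without both enzyme families. In SKO 15571 WT peaks (21.9%, 21.6% to 22.2%) were missing and 3911 SKO peaks (6.59%, 6.39% to 6.79%) had no WT peak. The strongest WT peaks missing lay 16.5 kb from Ngdn, a translation regulator of neurons (chromosome 14, 55040434 to 55040929, fold 22.9), inside Eif2ak1, the haem-regulated kinase of translation initiation (chromosome 5, 143897929 to 143898343, fold 22.2), inside Stox2 (chromosome 8, 47350492 to 47350911, fold 18.1) and inside Ppp1r37, a regulator of protein phosphatase 1 (chromosome 7, 19543629 to 19544006, fold 17.4), with the peaks near Tmem178 and H19 making up the 6. Those at Ngdn, Eif2ak1, Stox2 and Ppp1r37 were present in TKO.

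The strongest SKO peak absent from WT lay inside Ankrd42 (chromosome 7, 92630217 to 92630566, fold 22.8). Others lay near Kctd12b (X, 153636266 to 153636595, 48.7 kb away, fold 13.9) and near Cog2, a subunit of a Golgi tethering complex (chromosome 8, 124514948 to 124515317, 5.67 kb, fold 13.5). A TKO peak overlapped each of these 3. A further peak on chromosome 2 (80762218 to 80762500, fold 16.9), with no protein-coding gene within 100 kb, was also in TKO, and one on chromosome 10 (102867011 to 102867286, fold 14.4) was in SKO alone.

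By gene, Cdh13, a cadherin without a cytoplasmic domain (1185 kb), lost 17 of 47 WT peaks in SKO, Nav2 14 of 36, Asic2 13 of 36 and Rere 12 of 24. Gains reached 4 at Usp37 (a deubiquitinase, 7 SKO peaks), Fntb (a farnesyltransferase subunit, 9), Pxn (paxillin of focal adhesions, 9) and Gm2446, where all 4 SKO peaks were absent from WT.

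Weak peaks again made up most of the loss, with 76.9% (75.9% to 77.9%) of the weakest decile missing and 182 of the 35537 WT peaks above the median (0.512%, 0.443% to 0.592%). In the strongest decile 1 of 7107 was missing. Gained SKO peaks lay at a gene end in 16.9% of cases (15.8% to 18.1%), against 9.73% of shared SKO peaks of the same strength (8.67% to 10.9%), and lost WT peaks in 7.40% (7.0% to 7.82%), against 11.5% (10.6% to 12.3%).

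**Figure D3:**
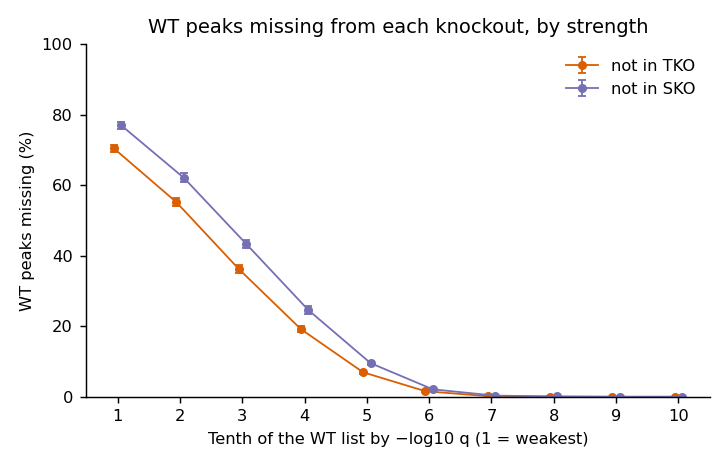
Share of WT peaks without a TKO or SKO peak (vertical axis, percent) in each decile of the WT list by −log10 q (horizontal axis), with 95% Wilson intervals. The share falls from 70.4% (TKO) and 76.9% (SKO) in the weakest decile to 0 of 7107 and 1 of 7107 in the strongest.

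**Figure D4:**
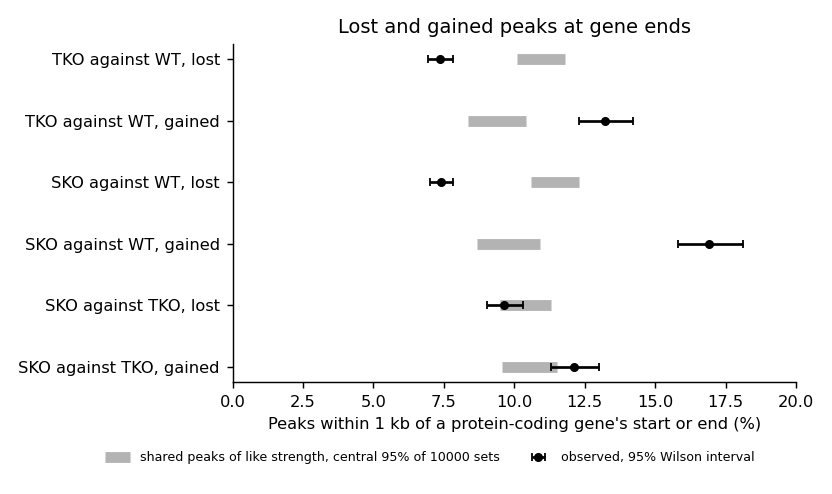
Share of lost and gained peaks within 1 kb of a protein-coding gene's start or end (horizontal axis, percent) for the 3 comparisons (vertical axis). Points carry 95% Wilson intervals and grey bars show shared peaks of the same list and strength; gained peaks of SKO against WT (16.9%) lie farthest above their bar.

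Imprinted genes lost more WT peaks in SKO than sets of the same strength, 33 of 140 where matched sets lost 24.5 (percentile 99.5). Zfp64 lost 5 of 16, Gnas 3 of 6, Trappc9 3 of 10 and the splicing factor gene Snrpn 3 of 9. Clustered protocadherins, cell surface genes whose promoters are known CTCF targets, lost fewer, 4 of 85 (9.77 in matched sets, percentile 0.345). Early lineage genes lost 9 of 81 (16.0, percentile 0.450), with 2 of 8 at the endoderm factor gene Gata4 and both at the laminin gene Lamb1. The imprinted value lay inside the central 95% for gene bodies alone (percentile 96.8), with 50 kb either side (70.3) and at a −log10 q of at least 5 (93.5). The protocadherin value did so with summits within 100 bp (percentile 12.9), and the early lineage value with that rule (3.25) and for gene bodies alone (5.85).

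The other lists stayed inside the range for losses in SKO with genes and 10 kb either side. Under an alternative, methylation enzymes and readers with 50 kb either side (23 of 155, 32.6 in matched sets, percentile 0.555) and the X inactivation centre with gene bodies alone (percentile 1.08) lay below it. Pluripotency genes lost 25 of 92 peaks (20.2 on average in matched sets, percentile 94.7, 99.1 with 50 kb either side and 98.6 with summits within 100 bp), with 5 of 10 at Esrrb, 3 of 9 at Nanog, which encodes a core pluripotency factor, and 2 each at Dppa4 and Gdf3. NuRD genes lost 18 of 90 (21.8), with 4 of 19 at Zmynd8 and all 3 WT peaks at Sall1. Germline genes lost 30 of 103 (28.5), of which the meiosis gene Tex15 had 6 of 7. Chromosome architecture genes lost 20 of 85 (22.1), retrovirus silencers 18 of 77 (17.6), methylation enzyme and reader genes 11 of 58 (12.9), Hox genes 5 of 34 (6.32), feeder fibroblast markers 9 of 58 (11.4), the X inactivation centre 5 of 23 (8.47) and genes of the 2-cell-like state 2 of 18 (2.75). Gains in SKO were fewer than in matched sets for architecture genes (1 of 66 SKO peaks, 5.27 expected, percentile 1.02) and early lineage genes (1 of 72, 4.38 expected, percentile 2.46). Both lay inside with 50 kb either side (percentiles 44.4 and 4.32) and at a −log10 q of at least 5 (11.5 and 20.7), as did early lineage genes with summits within 100 bp (11.4); germline genes lay above at a −log10 q of at least 5 (98.5). Over the 78 combinations of list, comparison and direction, 2 lay above and 8 below the central 95%, where 3.90 in all would come by chance, and 0 of these 10 lay outside it under each of the 4 alternatives for gene lists. The sets were matched on strength and not on nearness to genes, while gene ends lost fewer WT peaks at like strength. A low value for losses therefore does not single out a list from other genes.

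The imprinting control region between H19 and Igf2, which binds CTCF on the maternal chromosome and insulates Igf2 from enhancers, differed between the lists. WT had 2 peaks there on chromosome 7, at 142580068 to 142580955 (fold 15.8) and 142581631 to 142582184 (fold 17.6), with summits 2.58 kb and 3.74 kb past the boundary of H19 that faces Igf2. Over the first, TKO had a peak of fold 2.69 and −log10 q 1.55 (142580211 to 142580419), and SKO had none. Over the next, neither knockout had a peak. All 3 lists held the neighbouring peaks at 142610535 to 142610938 (WT fold 13.5), 142672175 to 142672474 (11.5) and 142675664 to 142676003 (14.1), the last 2 beyond Igf2. Around Dlk1 and Meg3, another imprinted pair on chromosome 12, the peak of highest −log10 q in WT (109542803 to 109543242, fold 23.2) was in all 3 lists. It lies in the strongest WT decile, where 0 of 7107 peaks were missing from TKO and 1 of 7107 from SKO. Its presence therefore does not set this locus apart from H19. Among weaker WT peaks there, 109566646 to 109566990 (fold 5.44) was missing from TKO. Those at 109539004 to 109539264 (fold 4.25) and 109609124 to 109609353 (fold 5.61) were missing from SKO. This locus was picked after its values were seen.

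**Figure D5:**
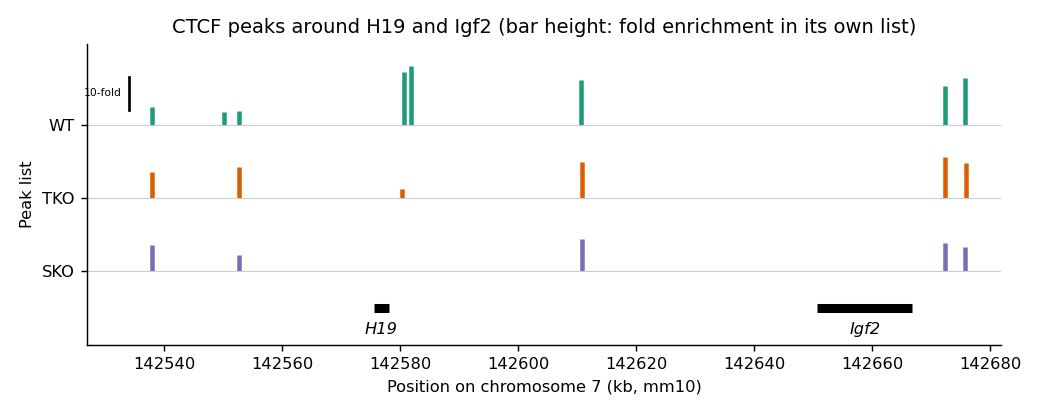
CTCF peaks around H19 and Igf2 on chromosome 7 (horizontal axis, kb, mm10), with 1 row per list; bar height is the fold enrichment in that list, and the scale bar is 10-fold. The WT peaks of fold 15.8 and 17.6 beside H19 have a TKO peak of fold 2.69 and no SKO peak over them, while the peak at fold 13.5 in WT is in all 3 lists.

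WT peaks lost in TKO were compared with those lost in SKO. Both knockouts lacked 9934 WT peaks, where independent losses would share 2956, and losses independent within 10 bins of WT strength 7791. Unchanged lists simulated from the WT pileups at each knockout's depth shared 473 losses over 20 draws. This value holds the counting noise of the knockouts alone. It takes the WT pileups as true, without their own noise or the choice of peaks that passed the WT threshold. It holds no variation between cultures or immunoprecipitations either, so unchanged lists could share more losses. Part of the excess may come from the WT list being common to both comparisons. Of the 13492 WT peaks missing from TKO, 3558 (26.4%, 25.6% to 27.1%) were present in SKO, and among those above the median WT strength 99 of 127 (78.0%, 70.0% to 84.3%). In the other direction, of WT peaks missing from SKO, 36.2% (5637 of 15571) were present in TKO, and 84.6% above the median (154 of 182). The peaks missing from both are common to these pairs of shares, so the higher share in the second direction follows from the larger number lost in SKO. Of gained peaks, 1304 of 4663 in TKO (28.0%, 26.7% to 29.3%) were also in SKO.

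The remaining comparison set the knockouts against each other. Of TKO peaks 8996 (14.5%, 14.2% to 14.7%) were missing from SKO, and 6165 SKO peaks (10.4%, 10.1% to 10.6%) were missing from TKO. The strongest TKO peaks missing from SKO lay near Wdr19, a ciliary transport protein (15.0 kb, fold 17), Dclk3 (17.9 kb, fold 14.9), Gfi1b, a transcription factor of blood formation (4.11 kb, fold 14.3), and Il9r, an interleukin receptor (9.74 kb, fold 13.8), inside Dupd1 (fold 14.2) and near Arhgap12 (30.0 kb, fold 13.5). All 6 were also in WT. The strongest SKO peaks missing from TKO lay inside Gm13283 (chromosome 4, 88760680 to 88760896, fold 18.6), inside Negr1, a neuronal adhesion protein (fold 15.6), near Apold1 (25.5 kb, fold 14.8), inside N4bp2l2 (fold 14.4) and near Map2, a dendritic microtubule protein (70.5 kb, fold 13.9), all in WT, and at the SKO-only peak on chromosome 10.

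Pluripotency genes lost more TKO peaks in SKO than matched sets, 21 of 84 where those lost 13.9 (percentile 99.6), with 5 of 8 at Esrrb and 2 of 4 at Nr5a2; at a −log10 q of at least 5 the percentile was 94.6, inside the central 95%. The X inactivation centre lost 1 of 19 (4.49 in matched sets, percentile 0.925) and early lineage genes 4 of 70 (8.32, percentile 2.1). Retrovirus silencers gained 1 of 59 SKO peaks (5.56, percentile 0.560). The retrovirus silencers lay inside under all 4 alternatives (percentiles 2.90 for gene bodies alone, 21.3 with 50 kb either side, 2.94 at a −log10 q of at least 5 and 4.58 with summits within 100 bp), the X inactivation centre at a −log10 q of at least 5 (17.9) and with summits within 100 bp (12.1), and early lineage genes with that rule (7.58) and for gene bodies alone (8.15). Outside under an alternative alone were germline genes at a −log10 q of at least 5 (24 of 84 lost, percentile 99.6, and 97.8 for gains), protocadherins for gene bodies alone (0.755 for losses) and with 50 kb either side (2.44), genes of the 2-cell-like state with summits within 100 bp (97.7 for losses) and methylation enzymes and readers with 50 kb either side (1.61 for gains). The genes with most losses included Cdh13 (10 of 40 TKO peaks), the postsynaptic scaffold gene Dlgap1 (8 of 26) and Anks1 (7 of 15). Those with most gains were Gm13276 (6 of 11 SKO peaks), Magi2 (6 of 16), and Gm38667 (6 of 82) and Gm38666 (6 of 83), which overlap each other and the clustered protocadherin genes. Gained SKO peaks lay at a gene end in 12.1% (11.3% to 13%) against 10.6% of shared peaks of the same strength (9.57% to 11.5%), a difference that lay inside the range with a window of 2.5 kb (percentile 96.2) and with all gene biotypes (94.8). At a −log10 q of at least 5 it lay above (99.9). Lost TKO peaks lay there in 9.63% against 10.4%, inside the range (percentile 4.99). Their percentile was 0.140 with 2.5 kb, 1.06 with all gene biotypes and 74.9 at a −log10 q of at least 5.

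Among the 20 chromosomes tested, 6 lost more WT peaks in SKO than the central 95% of matched sets and 4 lost fewer, and in TKO 2 lost more and 1 fewer, where 0.50 each would come by chance. At a −log10 q of at least 5 the counts were 2 and 4 in SKO and 3 and 3 in TKO. Chromosome 14, chosen after its values were seen, lost more WT peaks than its peak strengths would give in both knockouts, 22.1% (exact interval 20.7% to 23.7%) against 19% in TKO and 25.8% (24.3% to 27.4%) against 21.9% in SKO. It also gained fewer, 6.44% against 7.66% in TKO (percentile 0.330) and 5.31% against 6.52% in SKO (percentile 0.295). Its losses of TKO peaks in SKO lay inside the range (percentile 66.8). The X chromosome, also chosen after its values were seen, lost 24.6% (22.7% to 26.6%) in TKO, close to the 25.4% its strengths would give, and 24.9% (23.0% to 26.9%) in SKO, below 29.3%. Its gains against WT were 9.26% in SKO, above 7.86% (percentile 98.9), and inside the range in TKO (percentile 9.44). The causes were not tested. Lost WT peaks had a lost nearest neighbour in 20.9% of cases in TKO, inside the range of matched sets (19.7% to 21.1%), and in 24.7% in SKO, above it (22.7% to 24.1%).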

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

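No paired analysis was possible because the replicates of each genotype were pooled before peaks were called, and for the same reason no replicate could be left out. Planned comparisons that need the genome sequence (motifs, CpG density and repeats) were not run. Of the alternative values of counts that answer a comparison, 92 lay within 1.5 times the main count and 28 did not. Lost peaks outnumbered gained peaks in all 3 comparisons under each planned setting except the 30000 strongest peaks of each list, where equal lengths fix the balance.

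With a reciprocal overlap of 50%, WT peaks above the median strength missing from TKO rose to 582 and from SKO to 707; with summits within 100 bp they were 315 and 407. The WT peaks that the 50% rule adds still had a knockout peak over them by at least 1 bp. The summit rule likewise counts as missing a WT peak whose overlapping knockout peak has its summit farther away. Why overlaps or summits differed was not tested. At a −log10 q of at least 5 in all lists 66 were missing from TKO, with the median taken in the shorter list. Among the 30000 strongest peaks of each list, 3442 WT peaks were missing from TKO, 3757 from SKO, 3517 TKO peaks from SKO and 3547 SKO peaks from TKO; 1544 TKO-lost WT peaks were in SKO, 1898 regions were in WT only and 24633 in all 3 lists. With a −log10 q of at least 10 in the queried list alone, the losses from WT were 3757 (TKO) and 4715 (SKO), the gains 781 and 497, the losses from TKO in SKO 2416 and the gains 1112; 1677 TKO-lost WT peaks were in SKO, and above the median of those WT peaks 13 and 28 were missing.

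Shortening the lists to the length of the shortest, chosen after seeing the data, left 6441 WT peaks missing from TKO and 7143 from SKO, with 7157 gained in SKO, 26 and 46 missing above the median of the shorter list, 3863 regions in WT only and 2682 in both knockouts only. Lists of equal length lose and gain nearly equal numbers by construction, so this setting does not test the excess of lost peaks. Other shares and counts, those of gene lists included, stayed within the interval of a share or 1.5 times a count in 61 cases and moved beyond it in 65; the named peaks are left out of these, because the settings can take partners away from a peak but give it none. In unchanged lists simulated from WT pileups taken as true, knockout counting noise left 1291 WT peaks uncalled at TKO depth and 2528 at SKO depth. These counts leave out noise in the WT list. The absence of a weak peak from a list does not show that CTCF was absent there.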

Other observations

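The tests on depth and enrichment in TKO, on enrichment in SKO and on the H19 region were chosen after the results they bear on were seen; the others were set before. Among WT peaks above the median strength on the autosomes and X, 28 were missing from both knockouts. After those near Tmem178 and H19 they included a peak on chromosome 16 inside Grik1, a kainate receptor gene (87922956 to 87923262, fold 14), one near the potassium channel gene Kcnj15 on the same chromosome (68.2 kb away, fold 13.8), one inside the adhesion receptor gene Adgrl3 on chromosome 5 (fold 13.4) and one inside Dpp6, a potassium channel partner, also on chromosome 5 (fold 13.1). In the other direction 1298 TKO peaks on those chromosomes were absent from WT and present in SKO, among them peaks inside Bbs7, a ciliary protein gene (TKO fold 11, SKO fold 5.91), and Ablim3, an actin-binding protein gene (10.5 and 5.63). These peaks were chosen after their values were seen.

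Gene families defined by the stem of their symbol, examined after the overlaps had been seen, gave 109 families with at least 20 genes and 20 WT peaks. In each knockout 1 family lost more WT peaks than the central 95% of matched sets and 8 lost fewer, where 2.73 of each would come by chance. These sets too were matched on strength and not on nearness to genes, so fewer losses do not single out a family from other genes. The family that lost more in TKO had the Arhgef stem (36 of 140 peaks, 28.6 in matched sets, percentile 98.0, and 66.9 in SKO). In SKO it had the Cdh stem (40 of 156, 32.1, percentile 98.3, and 49.3 in TKO). Among those that lost fewer were genes with the Rab stem, named for vesicle traffic proteins, in SKO (48 of 247 peaks, 61.7 in matched sets, percentile 0.225, and 32.6 in TKO) and genes with the Rgs stem, named for regulators of G protein signalling, in TKO (5 of 75, 11.6, percentile 0.285, and 3.59 in SKO).

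More WT peaks were lost than gained in each knockout, 13492 against 4663 in TKO and 15571 against 3911 in SKO. Lower depth was argued against in TKO, whose background was 1.04 times that of WT. In SKO 3.73 WT peaks were still lost per gained peak after scaling to the SKO background. That scaling cut the WT list from 71075 to 70387 peaks, while the simulation at SKO depth left 2528 uncalled. It may correct for depth only in part, so the share of depth in the SKO losses stays open. Lower ChIP enrichment may account for the TKO list, since pileup over background at regions in all 3 lists was 0.885 times that of WT (0.876 to 0.891 over 1000 resamplings of regions), which weaker CTCF binding throughout would give as well. In SKO that ratio was 1.00 (0.990 to 1.00). The background in it is the local one at each peak, a measure chosen after the data were seen. The fold itself, the measure first set for this test and counted then as in favour of lower enrichment, gave 0.919. It carries a pseudocount of 1, and depth alone would bring it to 0.945. Median pileup at regions in all 3 lists was 40.0 in SKO and 56.0 in WT, at genome-wide backgrounds of 1.37 and 1.76. Over that background it would be lower in SKO, so lower enrichment in SKO stays open. The genotype stays open as an untested explanation, as does the depth of the inputs.

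WT peaks missing from TKO were mostly missing from SKO too. Independent loss of weak peaks cannot be told apart from linked loss: the shared losses were 1.26 times those expected within 50 bins of WT strength, but the limit set beforehand left out error in the WT list, which raises this ratio too, and with the TKO and SKO lists in its place it was 1.4 and 1.67. Chance highs in the WT list, against which both knockouts were read, are a candidate explanation: the odds ratio of being missing from both other lists was 4.51 for WT, 3.89 for TKO and 5.54 for SKO peaks, so that of WT was 0.814 times the higher of the others. DNA methylation that SKO lacks stays open as a route of loss in TKO. The shares of TKO-lost WT peaks present in SKO were 26.4% of all and 78.0% of those above the median. These shares were not set against a value free of selection, and methylation was not measured here. For the 15571 WT peaks missing from SKO, 9934 of them also missing from TKO, methylation is argued against as the route in SKO. Per the labels SKO lacks the methyltransferases.

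The H19 control region had 2 WT peaks, of which 1 had a TKO peak over it, with a summit more than 100 bp away, and 0 an SKO peak. Weaker ChIP over the whole locus was argued against in both knockouts, with pileup taken over the genome-wide background. Over the other 9 WT peaks within 100 kb, the median ratio to WT was 0.984 in TKO and 0.925 in SKO. In these medians 1 weak peak that neither called was taken as 0. Among the 8 called in both the lowest ratio was 0.834 in TKO and 0.603 in SKO, while at the control region it was at most 0.217 and 0.210, the highest value that would have gone uncalled standing in where no peak was called. Methylation of the sites, deletion of the region and lost binding for another reason stay open in TKO. They were not tested, since the peaks over the sites are the pattern itself. In SKO deletion and lost binding for another reason stay open likewise. Methylation of the sites is argued against there, since per the labels SKO lacks the methyltransferases, though methylation was not measured.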
